A study of Schizosaccharomyces pombe with 12 samples.

How the data were processed

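The series comprises 12 ChIP-exo samples in 6 groups of 2, grouped by the titles in the labels. Reads were aligned with Bowtie2, per the submitters' processing notes, and the build named there is ASM294v2; the version of Bowtie2, the read length and all further steps are not given in the sources used here. The 2 files analysed hold no measured value of any sample. The signal of the samples and the modified genome sequence were not analysed here, so the depth of each library is unknown and no test between groups was run. Replicate numbers in the labels were therefore not used.

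The first file is the inserted sequence as deposited, 1 line of bases. The second is the deposited annotation of the modified genome in BED form, with a chromosome, start, end, name, score and strand for each of 7002 features; the score is 0 throughout. How the authors made the intervals is not given in the sources used here. Coordinates are given 1-based, as the deposited BED start plus 1, and refer to the modified ASM294v2 genome unless the reference is named.

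Feature names without their transcript suffix were matched, ignoring case, to the locus tags of the RefSeq annotation of ASM294v3, and 6840 of 7002 matched. The 162 others were 27 mitochondrial features, 5 on AB325691, 2 added for the insert (Cutsite and Hph) and 128 other nuclear features, 111 of them named SPNCRNA. In 6 matched features the strand differed from the reference. The deposited build is ASM294v2 and the reference ASM294v3. Before reference sequence was joined to deposited coordinates, the nuclear chromosomes were compared: the highest deposited end equalled the reference length on chromosomes I (5579133) and III (2452883) but was 4534741 on chromosome II, below its length of 4541646 with the insert, so the length of chromosome II was not checked this way, and feature ends were compared per chromosome. The modified chromosome II was rebuilt by placing the insert in the reference where the Hph interval puts its reading frame. The mitochondrial and AB325691 features were left out of positional comparisons. Deposited starts mostly lay 1 base before the reference start (2839 of 4340 on chromosomes I and III) and were used as deposited.

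The recognition site of I-PpoI, 15 bases taken from general knowledge, was searched on both strands of the insert and the reference, exactly and with up to 2 mismatches. Reading frames ran from ATG to a stop codon with at least 100 codons. The break site is the centre of the recognition site in the insert. Features overlapping the 10 kb on each side were counted there and at 10000 random nuclear positions (seed 1), weighted by chromosome length and at least 20 kb from chromosome ends. Opposite-strand overlap meant at least 1 shared base, and shares have 95% Wilson intervals, which treat features as independent although neighbouring features share overlaps. The rule for named features took all features of the insert, up to 12 on each side within 10 kb, the genes named in the labels (rnh1, rnh201, ssb2, nmt1), and up to 10 features holding further recognition sites. These choices were made before the data were examined, as were the alternatives: 50 or 150 codons, 1 or 2 mismatches, 5 or 20 kb, features wholly inside the window, features of the insert left out, random positions on chromosome II only, an overlap of 100 bases or of 50% of the feature, and 1 feature per name. Added after the data were seen were starts moved by 1 base and the RefSeq annotation in place of the deposited one. The latter was counted on the unmodified chromosome around the insertion point, and then in modified coordinates with Cutsite and Hph and the same window, where every RefSeq gene of chromosome II ending right of the insertion point was moved whole by the insert length. Counting, overlap, site search and reading frame functions were tested on simulated data with known answers. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.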

Results

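The study used an inducible break system in the fission yeast Schizosaccharomyces pombe, in which the homing endonuclease I-PpoI cuts a site placed in the genome. It profiled 12 ChIP-exo libraries, a form of chromatin immunoprecipitation in which an exonuclease trims the recovered DNA to the edge of the bound region. The libraries fell into 6 groups of 2. In 4 libraries the S9.6 antibody, which binds RNA-DNA hybrids, was used in cells lacking rnh1 and rnh201, which encode ribonuclease H enzymes that degrade such hybrids, with I-PpoI on (n = 2) or off (n = 2). In the other 8 libraries Flag-tagged Ssb2, a subunit of the single-strand DNA binding complex RPA, was recovered: from wild-type cells with I-PpoI off (n = 2) or on (n = 2), from cells lacking rnh1 and rnh201 with I-PpoI on (n = 2), and from cells carrying rnh1 under the nmt1 promoter with I-PpoI on (n = 2). These groups imply 3 questions: whether hybrid signal differs with the break, whether Ssb2 signal differs with the break, and whether Ssb2 signal at the break differs with the level of ribonuclease H. The signal and depth of the 12 libraries were not analysed here, so no value, error or test is given for these 3 comparisons. The data analysed were the sequence of the inserted break system and the annotation of the modified genome, which set where the break lies and which features any signal around it would be assigned to. Neither has replicates.

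The break site lay on chromosome II between arg6, an arginine biosynthesis gene, and the coding sequence of ura5, which encodes orotate phosphoribosyltransferase of pyrimidine synthesis. Both genes and the inserted marker are on the plus strand. The insert was 1842 bases long and, by the Hph interval, occupied positions 1231079 to 1232920 of modified chromosome II (build ASM294v2 with the insert). It held 1 exact copy of the I-PpoI recognition site, CTCTCTTAAGGTAGC, at bases 11 to 25 counted from 1 at its first base, which is 1231089 to 1231103 on the chromosome. The annotation carried 2 features for the insert. The first, named Cutsite, spanned 31 bases from 1231085 to 1231115 and contained the recognition site. The second, named Hph, spanned 1231570 to 1232598 and matched a reading frame of 342 codons from bases 492 to 1520 of the insert; hph is the hygromycin resistance marker. One other reading frame of at least 100 codons was present, on the minus strand opposite Hph, with 271 codons from bases 438 to 1253. The centre of the recognition site was 474 bases from the start of Hph, 181 bases from the annotated end of arg6 and 1786 bases from the annotated start of ura5.

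**Figure D1:**
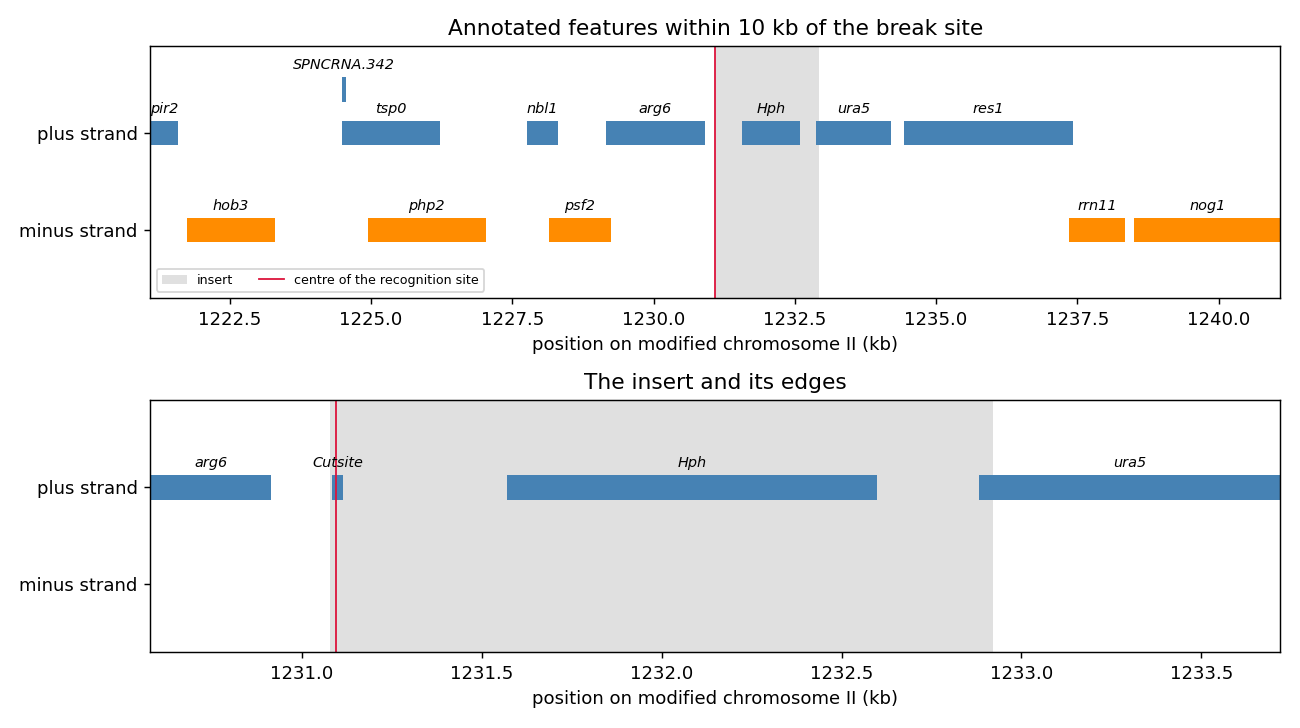
Annotated features of modified chromosome II around the break site, by strand (blue, plus; orange, minus) against position in kb. The upper panel covers 10 kb on each side without the 31-base Cutsite feature and with SPNCRNA.342 drawn above tsp0, which it overlaps; the lower panel enlarges the insert (grey), where the annotated ura5 interval starts 39 bases before the insert ends.

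Placed by the Hph interval, the insertion point fell directly before the start codon of ura5. In the unmodified reference (ASM294v3, chromosome II) the last base before the insert was 1231078 and the coding sequence of ura5 started at 1231079, with 36 annotated bases of 5′ untranslated region before it. The reference sequence to the right of the insert began ATGTCTTATAAA. The deposited ura5 interval, 1232882 to 1234200, lay wholly to the right of the site, and its first 39 bases covered the end of the insert. The Cutsite interval gave the same insert start as Hph when it was taken to begin right after the first GGATCC of the insert. That starting point was assumed, so the match is not an independent derivation. Both intervals also lie inside the insert, so the match does not check where the insert was joined to the chromosome. Moved back by the insert length, the deposited ura5 start was 1231040, against a gene start of 1231043 in the reference. The interval thus had about the place of the unmodified gene, untranslated region included, shifted whole by the insert length. With this placement such a shift gives the 39-base overlap, so the overlap does not require the placement to be off. It does not check the placement either, and the modified genome sequence that would was not analysed here. Features right of the insert were shifted by the full insert length: of 1834 features matched to reference loci there, 1167 (63.6%) had an end exactly 1842 bases beyond the reference end, and 0 had the unshifted end. Left of the insert, 443 of 666 features (66.5%) on chromosome II had ends equal to the reference, as had 2752 of 4340 (63.4%) on chromosomes I and III.

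Within 10 kb on each side of the break site the annotation held 14 features, of which 12 were other than Cutsite and Hph, 7 on the plus strand and 5 on the minus strand. On the left these were pir2, the fission yeast relative of the RNA-processing factor Ars2; hob3, a BAR-domain protein gene; tsp0; the short non-coding RNA SPNCRNA.342; php2, a CCAAT-binding factor subunit; nbl1, of the chromosomal passenger complex; psf2, of the GINS replication complex; and arg6. On the right they were ura5, res1, a subunit of the MBF transcription factor, rrn11, an RNA polymerase I initiation factor, and nog1, a GTPase of ribosome assembly. The nearest minus-strand features of the deposited annotation were psf2 and rrn11. Their nearer edges lay 1857 bases left and 6250 bases right of the site centre. The RefSeq annotation of ASM294v3 has nearer ones, the non-coding RNAs SPNCRNA.5080 and SPNCRNA.5081. Their nearer edges lie 191 bases left and 845 bases right of the insertion point on the unmodified chromosome. In the modified chromosome nearly all of the insert lies between the site centre and SPNCRNA.5081, which is therefore farther from the site than 845 bases. The coordinates were 1229152 to 1230915 for arg6, 1228147 to 1229239 for psf2, 1234429 to 1237429 for res1 and 1237346 to 1238347 for rrn11.

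The number of features around the break site was within the range of most genome positions. The 14 features compare with a median of 12 at 10000 random nuclear positions (5th to 95th percentile, 8 to 16), and 28.97% of random positions had at least as many. Without Cutsite and Hph the count was 12, which 60.39% of random positions reached. With the intervals as deposited, the nearest feature outside the insert was arg6, 181 bases from the site centre, a distance that 6.54% of random positions reached, while 86.28% lay inside a feature. Random positions outside features had a median distance of 163 bases, so by the deposited intervals 181 bases is not unusual for a position between features. The distance of 181 bases depends on the deposited ura5 interval lying wholly to the right of the site. With the placement above, the 5′ untranslated region of ura5 in the reference ends at the left edge of the insert, 18 bases from the site centre, and 12.8% of random positions were at least that far from a feature. In the unmodified reference, that placement puts the insertion point inside the ura5 gene, between its untranslated region and its coding sequence. The locus counts as lying between features only because the deposited ura5 interval was shifted whole. These shares describe a single locus and are not tests over replicates.

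**Figure D2:**
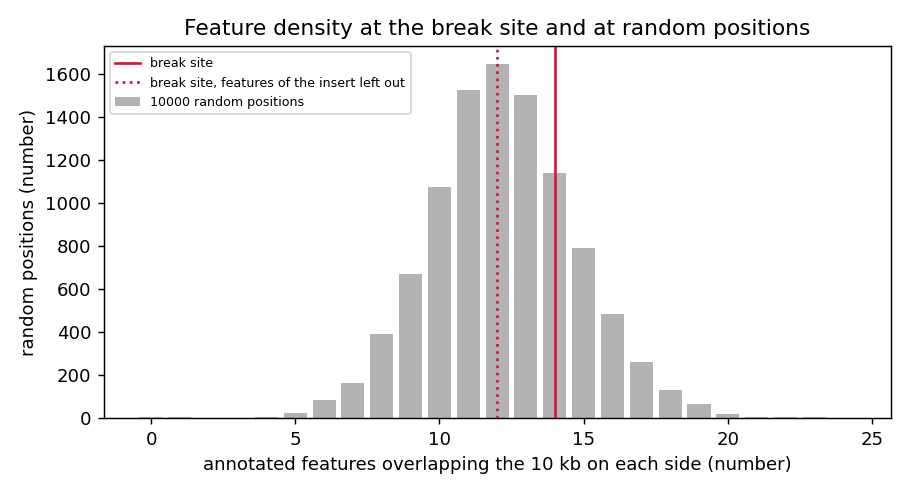
Number of annotated features overlapping the 10 kb on each side of a position (x axis) against the number of random positions with that count (grey bars, 10000 positions). The break site had 14 features (solid line), or 12 without those of the insert (dotted line), within the 5th to 95th percentile range of 8 to 16.

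Opposite-strand overlap, which limits how far signal can be assigned to a single gene, was common. Of 6970 nuclear features, 4191 (60.1%, 95% Wilson interval 59.0 to 61.3) overlapped a feature of the other strand by at least 1 base. Around the break site 7 of 14 features did so (50%, 26.8 to 73.2), an interval that includes the genome-wide share. All 7 were among the 12 features outside the insert. Cutsite and Hph lie in the insert, where no minus-strand feature was annotated. The overlapping pairs were tsp0 with php2 by 1278 bases, nbl1 with psf2 by 161 bases, psf2 with arg6 by 88 bases, and res1 with rrn11 by 84 bases. Cutsite, Hph and ura5 had no opposite-strand partner in the deposited annotation. In the RefSeq annotation, an alternative chosen after seeing the data, the genome-wide share was 89.2% and 25 of 25 features around the insertion point had a partner, ura5 among them with SPNCRNA.5081; that window is on the unmodified chromosome, without the insert, Cutsite and Hph. With the RefSeq genes moved to the modified coordinates, Cutsite and Hph kept and the window unchanged, it was 21 of 23. The features without a partner were then Cutsite and Hph. Features were listed without a score other than 0, so the intervals carry no measured level.

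The annotation held 7002 features: 3129 on chromosome I, 2552 on II, 1289 on III, 27 on the mitochondrial genome and 5 on the contig AB325691. By matched reference locus, 5101 were protein-coding, 1382 long non-coding RNA, 171 tRNA, 64 small nucleolar RNA and 47 rRNA genes. Plus-strand features made up 51.7% (95% Wilson interval 50.5 to 52.9). The genes named by the strain and antibody labels lay away from the break. On chromosome II, rnh1 spanned 2750330 to 2751876 on the minus strand, 1.52 Mb from the site. On chromosome I, rnh201 spanned 2254436 to 2255856 on the plus strand. On chromosome III, ssb2 spanned 1538389 to 1542108 on the minus strand, and nmt1, a thiamine-repressed gene whose promoter is used for regulated expression, spanned 1838334 to 1839525 on the plus strand. All 4 overlapped a feature of the opposite strand.

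The recognition site also occurred outside the insert. The reference genome held 3 exact copies, all on chromosome III and all within rRNA genes: 7177 to 7191 on the minus strand in SPRRNA.47, 18047 to 18061 on the minus strand in SPRRNA.48, and 2446063 to 2446077 on the plus strand in SPRRNA.49 (ASM294v3). The 3 genes were also in the deposited annotation. The natural target of I-PpoI is the large-subunit ribosomal RNA gene. Allowing 1 mismatch added 1 inexact match, in pdi4 on chromosome I at 3395609 to 3395623. Allowing 2 mismatches gave 16 matches in all, among them inexact ones in tel2, ulp1, mdh1, spt3 and the non-coding RNA meu3. How many inexact matches a genome of this size would hold by chance was not computed, so these are not shown to be targets. These counts are of the reference sequence, and how many copies of the ribosomal site the cells carry was not examined here. Whether any of these sites was cut was not measured in the files analysed.

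The insert differed from the surrounding genome in base composition. Its GC content was 54.2%, and that of the Hph reading frame 58.2%, against 36.1% for the nuclear reference, 37.65% for the 10 kb left of the insert and 36.1% for the 10 kb right of it. Among 10000 random reference windows of the insert's length the median was 35.99% and the highest 52.8%, so 0 windows reached the insert's value.

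**Figure D3:**
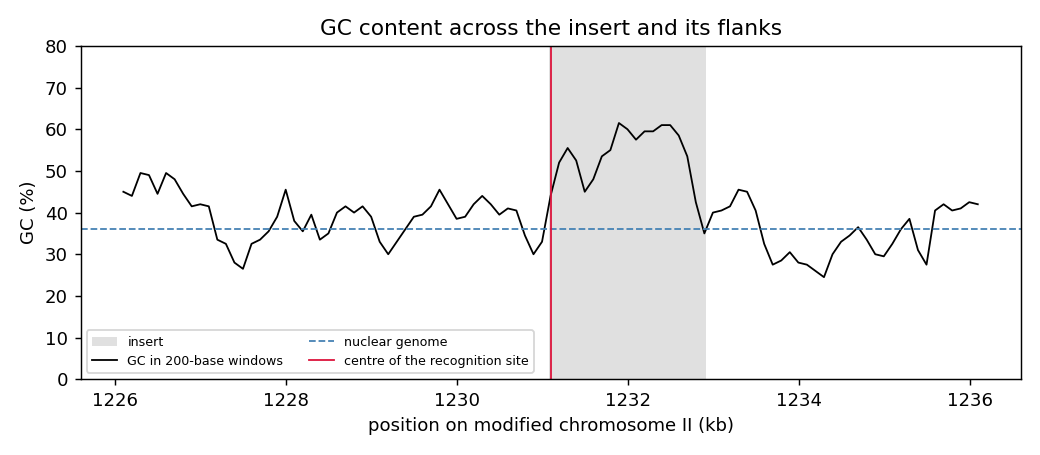
GC content in percent of 200-base windows every 100 bases (black line) against position on modified chromosome II in kb, over 5 kb on each side of the site centre (red), with the nuclear mean of 36.1% (dashed) and the insert (grey). Windows wholly inside the insert lay between 42.5 and 61.5%, and windows wholly outside it between 24.5 and 49.5%.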

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

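No paired analysis was possible because the files analysed hold no value of any sample. Of 29 alternatives to 7 results, 13 stayed within 1.5 times the count or percentile or within the Wilson interval of the share, and 16 did not. This tally is not a measure of robustness. The feature count around the break cannot change when only the random positions change. The Wilson interval is also far wider for 14 features than for 6970. The feature count around the break (14) was 9 within 5 kb, 25 within 20 kb, 25 in the RefSeq annotation on the unmodified chromosome and 23 in the RefSeq annotation moved to the modified coordinates; the first 2 follow from the window's size. The unmodified version changes the window as well as the annotation. Without the insert it loses Cutsite and Hph and reaches SPNCRNA.5085, SPNCRNA.5086, nit1 and SPNCRNA.1422. The moved version keeps Cutsite, Hph and the window. The share of random positions with at least as many features (28.97%) was 14.45% at 5 kb, 16.36% for features wholly inside the window, 60.39% without Cutsite and Hph, 17.99% with RefSeq unmodified and 37.58% with RefSeq moved; the break locus stayed between the 5th and 95th percentile of random positions throughout. The nuclear share with an opposite-strand partner (60.1%) was 49.4% at 100 bases, 30.2% at 50% of the feature and 89.2% with either RefSeq version, which lists 5751 nuclear lncRNAs that the deposited list lacks. Around the break (50%) it was 28.6% at 100 bases, 14.3% at 50% of the feature 100% (25 of 25) with RefSeq unmodified and 91.3% (21 of 23) with RefSeq moved. Up to 2 mismatches gave 16 matches to the recognition site in place of 3 exact ones. The RefSeq and moved-start alternatives were chosen after seeing the data, the moved RefSeq version after the values of the unmodified one. The smallest set, 14 features with Cutsite and Hph among them, gives a wide interval (26.8 to 73.2%), which includes the genome-wide share.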

Other observations

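The comparison of strand-free stretches was chosen only after the values were seen, while the start codon and short-window tests had their possible outcomes written down first. In the deposited annotation no minus-strand feature lay between 1229240 and 1237345, a stretch of 8106 bases. It holds most of arg6, the break site, Hph, ura5 and most of res1. The 1842 bases of the insert are part of this length, and the features annotated in the insert are all on the plus strand. The longer of the plus-free and minus-free stretches at random positions had a median of 3884 bases, and 17.43% of random positions had one at least as long. In the RefSeq annotation the minus-free stretch around the insertion point was 1035 bases, or 2877 with the insert added. It was bounded by the minus-strand long non-coding RNAs SPNCRNA.5080 and SPNCRNA.5081. Their nearer edges lay 191 bases left and 845 bases right of the insertion point on the unmodified chromosome. A further one inside the deposited stretch, SPNCRNA.5082, had its nearer edge 2673 bases right of the insertion point. Of the 25 RefSeq features within 10 kb, on both strands, 12 were not in the deposited list, and these 3 RNAs are among them.

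The deposited starts lay 1 base before the reference starts in 65.4% of the matched features on chromosomes I and III, while 10 of 4340 starts were equal. A candidate explanation is that the starts were lowered by 1 base beyond the BED convention. Among 3588 plus-strand nuclear features, Cutsite and Hph left out, an ATG stood at the second base of the interval in 271 and at the first base in 67, a ratio of 4.04. The Hph interval spans its reading frame exactly and so carries no such extra base. The 39-base ura5 overlap sets a deposited start against a placement by Hph and was not adjusted for the offset. A move of the reference starts instead would have put the ATG at the first base, where the count was 24.7% of that at the second, which argues against it. Right of the insert on chromosome II the second-base count was 71 of 977 in the rebuilt modified sequence and 18 of 977 in the unmodified one, so the same 1-base offset appeared once the insert was in place. For an assay read at single bases, such as ChIP-exo, profiles anchored on the left ends of these features would be displaced by 1 base.

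The deposited ura5 interval reached 39 bases into the insert. This holds for the insert as placed by the Hph interval. With that placement, shifting the unmodified ura5 interval whole by the insert length gives such an overlap. The overlap therefore does not require that placement to be off. It does not check that placement either, and the modified genome sequence was not analysed here. With that placement, the 36 bases of 5′ untranslated region of ura5 in the reference lie left of the insertion point and its coding sequence right of it, and signal on the 39 bases would be counted for ura5 although the sequence is that of the insert. Whether the strains transcribe ura5 from within or across the insert was not measured in the files analysed.

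The insert and the 3 ribosomal copies shared more than the recognition site: the identical run was 24 bases, with 4 bases before and 5 after the 15-base site. A window spanning the whole site and longer than that run cannot have a second exact place at these copies, so the count of 0 among 22 windows of 36 bases adds nothing to the run length. The hypothesis that such windows might have a second place within 2 mismatches was tested against the rebuilt genome on both strands. The closest other place of any of the 22 windows had 8 mismatches, which argues against it at 36 bases without gaps; the read length of the libraries and local alignment were not considered. A repeat elsewhere in the insert did give windows with a second exact place: a 72-base segment occurred at bases 62 to 133 and again at 134 to 205 of the insert. Of the windows touching the insert, 5.14% at 25 bases, 3.94% at 36 bases and 2.43% at 50 bases had a second exact place, and 0 of 1916 at 75 bases. All of them lay within bases 62 to 205, which starts 37 bases right of the recognition site.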
